A study of Sus scrofa with 6 samples.

How the data were processed

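The series holds bulk RNA sequencing of poly(A) RNA from pig (Sus scrofa) embryonic stem cell lines. Per the labels, messenger RNA was isolated with oligo(dT) beads from 1 µg of total RNA and made into stranded paired-end libraries of 151 bp reads. Lines PA_1 and PA_3 come from parthenogenetic embryos and line IVF_1 comes from an embryo fertilised in vitro, with 2 libraries per line and 6 libraries in all. The labels do not say whether the libraries of a line come from separate cultures, so the p-values may measure technical spread only.

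The authors trimmed the reads with cutadapt 2.8 and aligned them with STAR 2.7.1a to the pig genome build Sscrofa11.1. The gene counter, its annotation release and its strand setting are not given in the sources used here. The deposited table gives read counts per gene (counts, not normalised), and its whole-number columns were the only values used for the comparisons. The table also holds RPKM, which the authors scaled by gene length and library total, and the authors' TPM, which has the same sum in each library within rounding. The RPKM and TPM columns were used only to check the units. The table has 54 more columns of per-sample values for other samples, which were not used.

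The table has 31908 genes. A gene symbol came from the table for 16698 genes, from the NCBI gene ID in the table's description for 1420 and from a table of gene IDs for 167, while 13623 genes had no name. A symbol stood on more than 1 gene in 87 cases. Of the symbols in the fixed lists, 48 were not matched, among them SOX2, SALL4, H19, MEG3 and XIST, and these are not analysed here. Counts in overlapping genes or close paralogs cannot be assigned from the table alone.

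Library totals were 28575817 and 18208997 counts in PA_1, 24300183 and 26803977 in PA_3, and 16608237 and 15248306 in IVF_1. A count of 0 in both libraries of a line was given an upper limit of 3 counts over the line, which is 0.063 CPM (counts relative to the library total) in PA_1, 0.060 in PA_3 and 0.094 in IVF_1. For SGCE, MAGEL2 and KBTBD6, which had 1 to 3 counts in a PA line, that level is given as a percent of IVF_1 with a 95% counting interval. Other genes with 1 to 3 counts in a line are given as counts. These limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

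Levels are CPM after TMM scaling, as mean ± SD of the 2 libraries of a line. Differential expression was tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, two-sided) in R 4.3.3, with 1 coefficient per line and no covariate. The 6 libraries were fitted together, which left 3 residual degrees of freedom. The edgeR filter filterByExpr, grouped by line, kept 15197 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05 and no fold minimum, and the biological coefficient of variation was 6.1%. Fold changes are log2 with their standard error (SE). The comparisons were PA_1 against IVF_1, PA_3 against IVF_1, PA_1 against PA_3, and the mean of the PA lines against IVF_1. The data hold 1 line from a fertilised embryo, so each comparison is one of lines and does not test the origin of the embryo. For a value taken on its own, 2 libraries against 2 allow no exact permutation p below 0.333.

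The comparisons, the gene lists and the rule for the genes named were set before the data were examined. The rule takes, for each comparison between lines, the 10 genes with the largest log2 fold change in each direction among called genes with a symbol, at least 5 CPM in the higher line and no overlap between the libraries of the lines. For the mean of the PA lines it takes 10 per direction that were also called the same way in each PA line, with the 5 CPM taken in the PA mean or in IVF_1. From the lists it takes every measured member of the imprinted, Y and X lists. From each other list it takes up to 4 members with the smallest adjusted p, plus POU5F1, SOX2, NANOG, OTX2, KLF4, TBXT, GATA6, SOX17, CDX2, GATA3, PAX6, COL1A1, KRT8 and KRT18. Genes named outside the rule are marked in the text as chosen after their values were seen.

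The 22 lists cover core pluripotency, naive state, primed and formative state, primitive streak and mesoderm, hypoblast and endoderm, trophoblast and amnion, neuroectoderm, germ cells, and fibroblasts as feeder cells would bring. They also cover imprinted genes expressed from the paternal or the maternal allele, Y-linked genes, X-linked partners of Y genes, and targets of WNT, of FGF and ERK, and of NODAL and activin. The allele of the imprinted genes is that assigned by the lists and was not measured in these lines. Others cover DNA methylation, glycolysis, the nuclear-encoded respiratory chain, heat shock and the unfolded protein response, and proliferation. Of the lists, 1 is not reported here, though it stays among those counted as tested or called. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes, two-sided and adjusted over the lists. Each list was also tested with the correlation estimated per list, and with fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. Member counts are given over all genes tested and, where they differ, adjusted over the list alone.

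The test was checked on 5 simulated data sets of 15197 genes at these depths, with 200 genes changed. In PA_1 against IVF_1, 63.2% of genes changed 1.5-fold and 80.2% of genes changed 2-fold were recovered, and 10.5% of the called genes were unchanged, which is above the nominal 5%. In PA_1 against PA_3, the recovered shares were 65% and 84.2%, and 9.8% of the calls were unchanged genes. With camera, 0 of 50 unchanged simulated lists were called, and a list of 20 raised genes was called. The simulated genes were drawn independently of each other, so this check could not show false calls that come from correlation between genes. Because the comparisons against IVF_1 share its libraries, the overlap of their calls was set beside 20 simulations of unchanged lines. In each, all libraries were simulated, and both comparisons used the same simulated IVF_1 libraries.

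The alternatives tried were DESeq2 size factors (RLE) in the same fit, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, the libraries of the compared lines only, a 2-fold minimum, and leaving out each library in turn. Mitochondrial genes left out, the IVF_1 libraries split between the PA lines for the overlap of calls (4 coefficients, 2 residual degrees of freedom) and the repeats of the list tests and of the X chromosome medians were added after seeing the data. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.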

Results

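Poly(A) RNA was measured in 3 pig embryonic stem cell lines kept in the serum-free medium that the labels call FIW. Lines PA_1 and PA_3 came from parthenogenetic embryos, which arise from an egg activated without sperm and so hold maternal chromosomes by descent, and line IVF_1 came from an embryo fertilised in vitro. Each line gave 2 libraries, with totals from 15248306 to 28575817 counts. Across 15197 genes, the correlation of libraries (Pearson r of log2(CPM + 1)) was 0.995 within PA_1, 0.997 within PA_3 and 0.997 within IVF_1. Between lines its mean was 0.98 for PA_1 and IVF_1, 0.976 for PA_1 and PA_3, and 0.965 for PA_3 and IVF_1, over genes that are not independent replicates. Mitochondrial genes took 12.23% and 12.15% of the counts in the PA_3 libraries, against 7.97% and 9.65% in PA_1 and 7.67% and 8.29% in IVF_1.

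The study asked about the identity of these cells, and all 3 lines held high levels of POU5F1, DNMT3B and OTX2 transcripts. POU5F1, a core pluripotency factor, stood at 637 ± 40.6 CPM in PA_1, 836 ± 62.9 in PA_3 and 811 ± 39.1 in IVF_1 (SD, n = 2 libraries per line, as for all levels). DNMT3B, a DNA methyltransferase of the post-implantation epiblast, stood at 1577 ± 74.1, 1582 ± 2.28 and 3135 ± 1.61 CPM in the same order, and OTX2, a factor of formative and primed cells, at 389 ± 47.1, 540 ± 0.681 and 359.8 ± 1.00 CPM. NANOG, another core factor, differed between the lines, with 30.6 ± 6.61, 10.7 ± 0.989 and 75.8 ± 1.06 CPM. TBXT, a factor of the primitive streak, had 0 counts in PA_1, 1 count in PA_3 and 0.38 CPM in IVF_1, and CDX2 of the trophectoderm had 0 counts in each library. GATA6 of the hypoblast stood at 0.231, 0.173 and 0.884 CPM in PA_1, PA_3 and IVF_1. COL1A1, a fibroblast collagen, stood at 35.1 ± 3.76, 35.8 ± 2.53 and 38.5 ± 1.66 CPM, and no comparison called it.

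**Figure D1:**
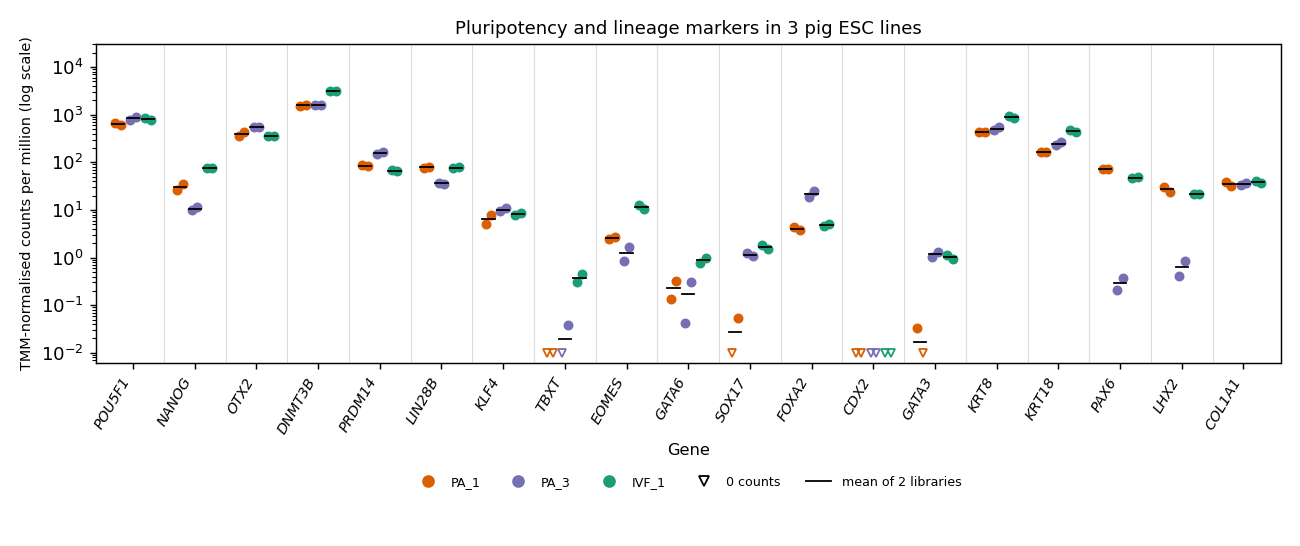
TMM-normalised CPM (log axis) of pluripotency and lineage genes in the 2 libraries of each line, with points for libraries, black bars for line means and open triangles at the foot for 0 counts. POU5F1 lies between 637 and 836 CPM on average in the 3 lines, whereas PAX6 and LHX2 lie below 1 CPM on average in PA_3.

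PA_1 against IVF_1 compared a parthenogenetic with a fertilised line, and the genes given first are imprinted genes expressed from the paternal allele. SNRPN, a splicing factor gene on scaffold AEMK02000602.1 (104535 to 142577), had 0 counts in PA_1 and 651 ± 14.0 CPM in IVF_1, at least 10371-fold lower. PEG10, a retrotransposon-derived gene on chromosome 9 (74474058 to 74486980), had 0 counts against 548 ± 21.6 CPM, at least 8736-fold lower. NNAT, which encodes the membrane protein neuronatin, fell from 1008 ± 45.9 CPM to 0.748 ± 0.099 CPM (log2 fold change -10.42, SE 0.12, adjusted p = 9e-20), and DLK1, a Notch ligand homologue, from 186 ± 9.05 to 2.0 ± 0.199 CPM (-6.52, SE 0.12, adjusted p = 3.1e-17). MAGEL2 and MEST fell less: MAGEL2 kept 18.8 ± 0.767 CPM against 100.3 ± 1.02 (-2.42, SE 0.1), and MEST kept 49.3 ± 1.81 CPM against 118 ± 1.39 (-1.26, SE 0.081).

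Of the 17 tested genes expressed from the paternal allele, 12 were lower and 1 was higher in PA_1, and adjusted over the list alone the counts were the same. The list's median log2 fold change was -6.52, or -6.09 with genes at 0 counts set at their bound (camera adjusted p = 1.9e-12). With an estimated correlation this gave adjusted p = 0.075, and fry gave an adjusted p of 7.6e-05. The 4 genes not called were IGF2, ZDBF2, DIO3 and RTL1, with IGF2 at 4.27 ± 0.249 CPM in PA_1 and 3.55 ± 0.0666 in IVF_1. INPP5F was the gene called higher (0.30, adjusted p = 0.0066), and the call was lost without replicate 1 of IVF_1 (adjusted p = 0.1). NAP1L5, a gene model annotated as a pseudogene in the table, had 0 counts in PA_1 and was at least 68-fold lower. SGCE had 2 counts, which is 0.24% of the IVF_1 level (95% counting interval 0.0359% to 1.07%). Of the 16 tested genes expressed from the maternal allele, 3 were lower and 0 were higher (2 lower adjusted over the list alone; camera adjusted p = 0.43, and fry adjusted p = 0.016, lower). IGF2R, which encodes a receptor that clears IGF2, was among them at -0.23 (adjusted p = 0.011), and the call was lost without either IVF_1 library (adjusted p = 0.13 without replicate 1 and 0.071 without replicate 2).

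**Figure D2:**
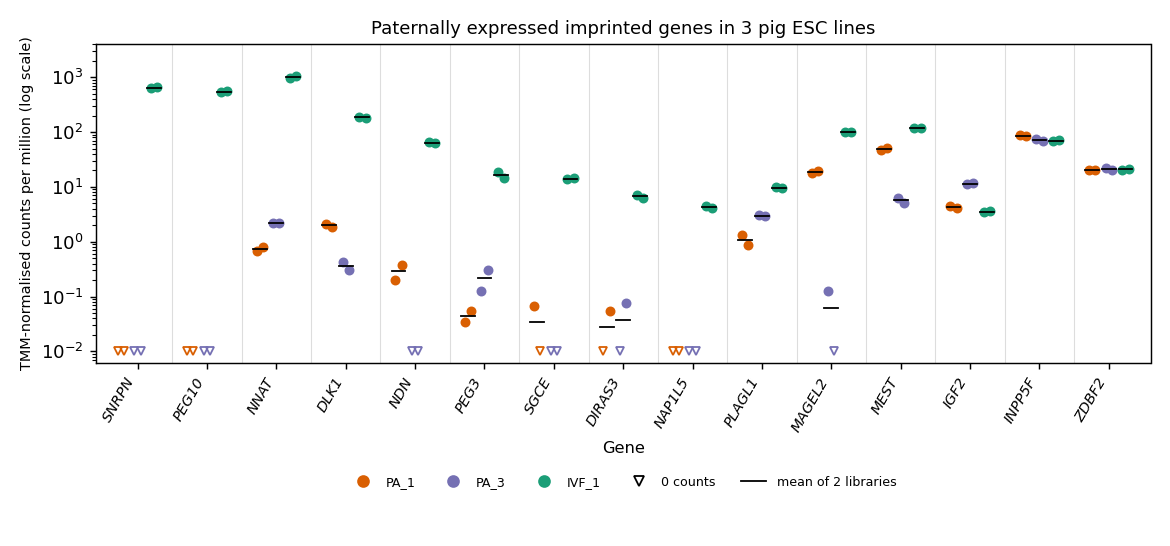
TMM-normalised CPM (log axis) of imprinted genes expressed from the paternal allele, with points for libraries, black bars for line means and open triangles at the foot for 0 counts. SNRPN and PEG10 have 0 counts in the 4 PA libraries, MAGEL2 and MEST are intermediate in PA_1, and ZDBF2 and INPP5F are near the same level in the 3 lines.

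Among pluripotency, trophoblast and signalling genes, camera called 5 lists lower in PA_1 than in IVF_1. Of 16 core pluripotency genes 8 fell and 1 rose, with NANOG at -1.32 (SE 0.12, adjusted p = 5e-07) and CDH1, the epithelial cadherin, at -0.47 (SE 0.066). Camera gave an adjusted p of 0.0052 for this list (adjusted p = 0.24 with an estimated correlation). Of 14 naive state genes 6 fell, among them STAT3 (-1.12) and PDGFA (-1.42), and 1 rose, ESRRB (1.06), with a camera adjusted p of 0.0057 (adjusted p = 0.35 with an estimated correlation). Of 14 trophoblast and amnion genes 8 fell and 0 rose (9 fell adjusted over the list alone), with the keratins KRT18 at -1.46 and KRT8 at -1.05 and the factor EOMES at -2.17 (camera adjusted p = 1.4e-05; adjusted p = 0.075 with an estimated correlation). Among 19 FGF and ERK targets 10 fell and 1 rose (11 and 1 adjusted over the list alone), including the feedback regulator SPRY4 (-2.14) and the factor ETV4 (-1.69), with a camera adjusted p of 4.5e-05 (adjusted p = 0.075 with an estimated correlation). Among 13 NODAL and activin targets 9 fell and 1 rose, including FST (-0.98) and SMAD7 (-0.73), with a camera adjusted p of 0.0016 (adjusted p = 0.24 with an estimated correlation).

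Of 22 heat shock and unfolded protein genes 15 fell in PA_1 and 0 rose, with the chaperones HSPD1 at -0.66 and HSPA8 at -0.49 (camera adjusted p = 1.4e-06; adjusted p = 0.075 with an estimated correlation). Of 17 neuroectoderm genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), among them STMN2 (1.83), SIX3 (0.65) and PAX6 (0.61), with a camera adjusted p of 0.0015 (adjusted p = 0.44 with an estimated correlation). Of 30 respiratory chain genes 8 fell and 1 rose, with SDHD at -0.61 and CYC1 at -0.43. Camera called this list (adjusted p = 0.0059; adjusted p = 0.56 with an estimated correlation), and the call was lost with fry (adjusted p = 0.065) and without replicate 1 of IVF_1 (adjusted p = 0.11). Of 26 proliferation genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with TYMS at -0.44. The adjusted p of this list was 0.029 (adjusted p = 0.49 with an estimated correlation), and 0.15 without replicate 2 of PA_1, 0.1 without replicate 1 of IVF_1 and 0.055 with the libraries of PA_1 and IVF_1 only.

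Camera called none of the other lists reported here in PA_1 against IVF_1. Primed and formative genes split with 7 higher and 9 lower of 25 (8 and 9 adjusted over the list alone; camera adjusted p = 0.21), and hypoblast and endoderm genes with 2 higher and 6 lower of 18 (0.21). Fibroblast genes had 4 higher and 8 lower of 24 (5 and 9 adjusted over the list alone; camera adjusted p = 0.21), with THBS1 at -1.01 and TAGLN at -1.17. Germ cell genes had 1 higher and 3 lower of 9 (0.21), with DND1, a germ cell RNA-binding protein, at -1.21. WNT targets had 3 higher and 6 lower of 16 (3 and 7 adjusted over the list alone; camera adjusted p = 0.17), with APCDD1 at 0.65 and CCND1 at -0.76. Primitive streak and mesoderm genes had 1 higher and 3 lower of 15 (3 and 3 adjusted over the list alone; camera adjusted p = 0.83), with a median of 0.20 and a mean of -0.09. DNA methylation genes had 3 higher and 2 lower of 17 (camera adjusted p = 0.99), and fry called the list lower (adjusted p = 0.016). Fry also called the primed and formative list (adjusted p = 0.01) and the WNT target list (adjusted p = 0.019) lower. ZFP57, a gene model annotated as a pseudogene in the table and named after a zinc finger protein that guards imprints, rose from 1.40 ± 0.321 to 9.31 ± 1.13 CPM (2.72, SE 0.24). DNMT3B fell (-0.99, SE 0.065). Glycolysis genes had 6 higher and 2 lower of 21 (6 and 3 adjusted over the list alone; camera adjusted p = 0.21, and 0.0022 without replicate 2 of PA_1), with LDHA, the lactate dehydrogenase subunit, at 1.24 (SE 0.17).

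In all, 4766 of 15197 genes passed the threshold in PA_1 against IVF_1, of which 2326 were higher and 2440 lower, and 551 and 455 of these changed at least 2-fold. Among called genes with a symbol and at least 5 CPM in the higher line, the largest fold changes upward were in DEDD2 (4.17, SE 0.33) and the potassium channel gene KCNK10 (3.22, SE 0.16). PAGE4 on the X chromosome was among the 10 largest downward by the same rule, with 0.105 ± 0.0052 CPM in PA_1 and 200.5 ± 1.12 in IVF_1. The total was 2307 without replicate 1 of IVF_1 and 2745 without replicate 2 of IVF_1.

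In PA_3 against IVF_1, the same 12 imprinted genes expressed from the paternal allele were lower, and DIO3 was too. SNRPN and PEG10 had 0 counts in PA_3 and were at least 10862-fold and at least 9150-fold lower, and NDN, a growth suppressor of the Prader-Willi region, had 0 counts against 64.6 ± 1.83 CPM and was at least 1078-fold lower. MAGEL2 had 3 counts in PA_3, which is 0.0628% of the IVF_1 level (95% counting interval 0.0123% to 0.174%). MEST fell from 118 ± 1.39 to 5.72 ± 0.761 CPM (-4.37, SE 0.1, adjusted p = 2.2e-15). PAX6, an eye and neural factor, fell from 47.3 ± 1.37 to 0.295 ± 0.121 CPM (-7.28, SE 0.17, adjusted p = 2.4e-15), and CDKN1A, a cell cycle inhibitor, from 50.2 ± 2.15 CPM to 0.12 ± 0.00827 CPM (-8.64, SE 0.32, adjusted p = 1e-10). LDHA rose from 81.2 ± 1.43 to 420.4 ± 56.9 CPM (2.37, SE 0.18, adjusted p = 7.6e-05).

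Of the 17 tested genes expressed from the paternal allele, 13 were lower in PA_3 and 1, IGF2, was higher (1.70, SE 0.16, adjusted p = 1.8e-07), with the same counts adjusted over the list alone. The median was -7.21, or -6.22 with genes at 0 counts set at their bound (camera adjusted p = 7.5e-09; adjusted p = 0.14 with an estimated correlation). Of the 16 tested genes expressed from the maternal allele, 4 were higher and 5 lower (camera adjusted p = 0.66, and fry adjusted p = 0.033, lower), with CDKN1C, a related inhibitor, at 0.79 (adjusted p = 0.0007) and IGF2R at -0.31 (adjusted p = 0.0005).

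Of 21 glycolysis genes 13 rose and 1 fell in PA_3, including ENO2 (1.5) and PDK1, which restrains pyruvate oxidation (0.91), with a camera adjusted p of 1.6e-04 (adjusted p = 0.62 with an estimated correlation). Of 19 FGF and ERK targets 11 fell and 2 rose, with ETV4 at -1.92 and SPRY1 at -1.28 (camera adjusted p = 0.0043; adjusted p = 0.26 with an estimated correlation). Of 13 NODAL and activin targets 9 fell and 0 rose, with NODAL at -2.48 and its inhibitor LEFTY2 at -1.87 (camera adjusted p = 0.0014; adjusted p = 0.27 with an estimated correlation). Of 14 trophoblast and amnion genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with KRT18 at -0.89 and EOMES at -3.22 (camera adjusted p = 0.029; adjusted p = 0.27 with an estimated correlation).

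Among 22 heat shock and unfolded protein genes in PA_3, 11 fell and 3 rose, with HSPA5, the chaperone of the endoplasmic reticulum, at -0.88 and HSPB1 at 0.94. The camera adjusted p of this list was 0.029 (adjusted p = 0.27 with an estimated correlation) and 0.05 without replicate 1 of PA_3, which ended the call. Among 17 DNA methylation genes 9 fell and 1 rose (9 and 3 adjusted over the list alone), with DNMT3B at -0.99 and the maintenance enzyme DNMT1 at -0.51. That list had a camera adjusted p of 0.049 (adjusted p = 0.27 with an estimated correlation), which was 0.05 without replicate 1 of PA_3, 0.052 without replicate 2 of PA_3 and 0.059 without replicate 1 of IVF_1.

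Among the lists that follow, camera called none in PA_3 against IVF_1. Core pluripotency genes had 3 higher and 8 lower of 16 (camera adjusted p = 0.064, but 0.023 without replicate 2 of IVF_1, 0.023 with no filter and 0.035 with the replicate block), with PRDM14 at 1.23, NANOG at -2.83 and LIN28B at -1.11. Neuroectoderm genes split with 6 higher and 8 lower of 17 (7 and 8 adjusted over the list alone; camera adjusted p = 0.41), with the forebrain factor LHX2 at -5.09 and STMN2 at 2.01. Hypoblast and endoderm genes had 9 higher and 3 lower of 18 (camera adjusted p = 0.26), with the endoderm factor FOXA2 at 2.18, a list median of 0.19 and a mean of -0.17. Fibroblast genes had 6 higher and 10 lower of 24 (camera adjusted p = 0.2), with the matrix protein TNC at -2.42 and THBS1 at -1.12. Proliferation genes had 4 higher and 11 lower of 26 (6 and 12 adjusted over the list alone; camera adjusted p = 0.16), with TYMS at -1.40 and PCNA at -0.76. Of these lists, fry called core pluripotency (adjusted p = 0.0048), fibroblast (0.031) and proliferation genes (0.023) lower. It called hypoblast and endoderm genes higher (adjusted p = 0.033).

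In PA_3 against IVF_1, 7920 genes passed the threshold, 3937 higher and 3983 lower, and 1171 and 820 of these changed at least 2-fold. Among the 10 largest upward of the called genes with a symbol and at least 5 CPM were UNC13C, a synaptic priming factor (18.4 ± 0.228 CPM against 0.126 ± 0.00708), and EXTL1 (5.12, SE 0.23). ATP8, a mitochondrial gene of the ATP synthase (MT, 8959 to 9162), had 1096 ± 84.1 CPM in PA_3, 1.24 ± 0.0627 in PA_1 and 1.29 ± 0.117 in IVF_1, and its annotated span overlaps that of ATP6 (9120 to 9800). TRIM4, a ubiquitin ligase gene, had 0 counts in PA_3 and was at least 340-fold lower than in IVF_1.

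PA_1 against PA_3 compared the parthenogenetic lines with each other. PAX6 (7.89, SE 0.17, adjusted p = 9.4e-16), LHX2 (5.42, SE 0.21) and SIX6 (4.71, SE 0.29), all factors of the eye field, were higher in PA_1. CDKN1A was also higher in PA_1 (6.89, SE 0.37, adjusted p = 8e-09), as were MEST (3.11, SE 0.1) and MAGEL2, which had 18.8 ± 0.767 CPM in PA_1 and 3 counts in PA_3. IGF2 was lower in PA_1 (-1.43, SE 0.14, adjusted p = 7.7e-07), as were FOXA2 (-2.40, SE 0.16) and LDHA (-1.13, SE 0.16). TRIM4 with 21.5 ± 1.20 CPM and ZNF175 with 6.43 ± 0.702 CPM in PA_1 had 0 counts in PA_3, and PAGE4 stood at 0.105 ± 0.0052 CPM in PA_1 and 376 ± 18.8 in PA_3.

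By list, 9 of 17 neuroectoderm genes were higher and 2 lower in PA_1 than in PA_3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0046; adjusted p = 0.72 with an estimated correlation). Of 21 glycolysis genes 13 were lower and 0 higher (14 and 1 adjusted over the list alone; camera adjusted p = 6.9e-05; adjusted p = 0.72 with an estimated correlation and 0.11 with fry). Of 18 hypoblast and endoderm genes 10 were lower and 1 higher (camera adjusted p = 0.015; adjusted p = 0.72 with an estimated correlation). Of 17 DNA methylation genes 6 were higher and 0 lower (8 and 0 adjusted over the list alone), with ZFP57 at 2.06 (camera adjusted p = 0.015; adjusted p = 0.54 with an estimated correlation). Genes expressed from the paternal allele had 6 higher and 3 lower of 17 (6 and 4 adjusted over the list alone; camera adjusted p = 0.35), with a median of 0.00 and a mean of 1.04. Fry called this list higher in PA_1 (adjusted p = 0.011). The mean includes fitted values for genes with 0 counts in PA_3, such as NDN at 5.59. In all, 5595 genes passed the threshold, 2712 higher and 2883 lower in PA_1, and the total was 3406 without replicate 2 of PA_3.

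Both PA lines differed from IVF_1 in the same direction in 1559 genes called higher and 1724 called lower. Lower in both were NNAT, DLK1, NANOG, DNMT3B, STAT3, KRT8 and KRT18, and higher in both were STMN2, the carbonic anhydrase gene CA14 (2.11 in PA_1 and 2.40 in PA_3) and the contactin gene CNTN1 (2.57 and 2.53). Independent lists of these sizes would share 603 and 640 genes, and unchanged lines simulated with shared IVF_1 libraries shared 0.25 and 0.35 genes on average. Few genes can be called where none is changed, so this low overlap was fixed in advance and is no baseline for the observed counts. The fold changes of the PA lines correlated across genes (r = 0.6, covariance 0.5078), against r = 0.56 and a covariance of 0.0323 in the simulation. In a test added after the data were seen, the IVF_1 libraries were split between the PA lines, with the spread estimated on 2 residual degrees of freedom. With library 1 for PA_1 and library 2 for PA_3, 748 genes were higher and 905 lower in both (231 and 258 for independent lists; r = 0.5, covariance 0.4899). With the libraries exchanged these were 690 and 799 (200 and 222; r = 0.49, covariance 0.4857). The split removes the counting error that the comparisons share through IVF_1 but not the state of that line, which both comparisons still have in common. Without replicate 1 of IVF_1 the shared counts were 761 and 833, and without replicate 2 of IVF_1 they were 852 and 1021.

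For the mean of the PA lines against IVF_1, 3287 genes were higher and 3526 lower, 6813 in total (3907 without replicate 1 and 4246 without replicate 2 of IVF_1). Among genes called higher in each PA line, with a symbol and at least 5 CPM in the PA mean, the largest fold changes were in EXTL1 (4.19, SE 0.24), UMODL1 (3.37, SE 0.17) and the transporter gene SVOP (3.27, SE 0.26). The largest fitted values downward, with a symbol and at least 5 CPM in IVF_1, were in SNRPN, PEG10 and KBTBD6, a ubiquitin ligase adaptor gene on chromosome 11 (25643709 to 25710987) with 0 counts in PA_1, 1 count in PA_3 (0.0758% of the IVF_1 level, 95% counting interval 0.00201% to 0.443%) and 25.1 ± 1.30 CPM in IVF_1. The rank of these genes rests on fits to 0 or 1 counts in a PA line. A gene model of GNAS, an imprinted gene in mammals with several promoters, on chromosome 17 (58985580 to 59053018) rose from 92.9 ± 6.90 CPM in IVF_1 to 340.4 ± 58.5 in PA_1 and 520 ± 25.01 in PA_3, and it overlaps another GNAS model, so reads of the shared exons cannot be assigned. The other model has more counts and stands in the list of genes expressed from the maternal allele, of which 0 were called higher in PA_1 than in IVF_1. The other model was thus not called higher in PA_1, and the rise is given for 1 gene model only. Whether GNAS as a whole rose cannot be told from these counts. Camera called 9 lists, among them genes expressed from the paternal allele (13 lower and 1 higher, or 13 and 2 adjusted over the list alone; adjusted p = 3.1e-11; adjusted p = 0.11 with an estimated correlation).

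Sex-linked genes and whole chromosomes were compared as a check of the labels. The Y-linked genes KDM5D, SRY and EIF1AY had 0 counts in each of the 6 libraries, IVF_1 included, so they could not separate the lines or check the labels. Of 129 gene models on chromosome Y, 46 had counts. They made up 0.0224% to 0.0279% of the counts in each library, the PA lines included, so these counts do not tell the lines apart. X-linked partners of Y genes had 2 lower and 0 higher of 11 in PA_1 (camera adjusted p = 0.75) and 3 higher and 3 lower in PA_3 (0.87) against IVF_1. The median log2 fold change of 528 X-linked genes was 0.068 in PA_1 and 0.105 in PA_3 against IVF_1, and that of single autosomes lay between -0.059 and 0.066. The X median minus the autosomal median was 0.075 in PA_1 and 0.114 in PA_3.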

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

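All tests in this part that weigh an explanation were chosen after the results were seen.

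Effects against IVF_1 that differed between PA_1 and PA_3 were singled out where the direct comparison of the PA lines also passed the threshold. In 161 genes PA_1 was higher and PA_3 lower than IVF_1, and in 121 genes the reverse held, against 610 and 632 for independent lists. The comparisons share the IVF_1 libraries and the state of that line, and both push fold changes the same way and lower such counts. The part of the libraries was small, with a covariance of 0.0323 in simulated unchanged lines against 0.5078 observed. Since the state of IVF_1 is in both comparisons, the shortfall against independent lists cannot be credited to the PA lines alone. Among the genes named for PA_1 against PA_3, 11 were called in opposite directions against IVF_1, namely GSTM3, VIPR2, FMN2, BBS10, PAX6, RALYL, PAGE4, AMY2, TNXB, S1PR5 and SRPX, and BBS10 lost its call in PA_1 against IVF_1 without replicate 2 of PA_1 (adjusted p = 0.087), without replicate 1 or 2 of IVF_1 (0.1 and 0.11) and with DESeq2 (0.085). Camera separated the PA lines in the hypoblast and endoderm list (adjusted p = 0.015), the neuroectoderm list (0.0046), the DNA methylation list (0.015) and the glycolysis list (6.9e-05), and with an estimated correlation the adjusted p was 0.72, 0.72, 0.54 and 0.72. IGF2 was lower in PA_1 than in PA_3 (log2 fold change -1.43) and above IVF_1 by a call in PA_3 alone. CDKN1A was higher in PA_1 than in PA_3 by a log2 fold change of 6.89 and lower than in IVF_1 in both PA lines.

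MEST and MAGEL2, expressed from the paternal allele in mammals, stood higher in PA_1 than in PA_3 by log2 fold changes of 3.11 and 8.16, the latter a fitted value against 3 counts in PA_3, while SNRPN, PEG10, SGCE, DIRAS3 and NAP1L5 of the same list had 0 to 2 counts in each PA line. RNA or cells of IVF_1 mixed into PA_1 would bring each abundant transcript in 1 ratio, but SNRPN, PEG10, NNAT, DLK1 and SGCE reached at most 1.07% of their IVF_1 level in PA_1, against 18.8% for MAGEL2 and 41.7% for MEST. A general release of genes silenced on maternal chromosomes is argued against by the summed count of SNRPN and PEG10 in PA_1, which was 0. A candidate explanation is a state of these loci that differs between the lines, through culture or through the embryos they came from, and no test of it was run.

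ATP8 was lower in PA_1 than in PA_3 by a log2 fold change of -9.76, with almost no counts in PA_1 and IVF_1. More mitochondrial RNA in PA_3 is argued against as the whole cause, because the largest log2 fold change among the other mitochondrial protein genes, PA_3 against IVF_1, was 1.5. Reads of the overlapping gene ATP6 counted to ATP8 in PA_3 cannot be told apart from a change of ATP8, since ATP6 lay -0.19 from the median of the others, where a shift of -0.14 would be needed and the SD among the 11 others was 0.36. ATP6 itself stood at 8196 CPM in PA_1 and 8267 in IVF_1, where ATP8 stood at 1.24 and 1.29 CPM. Reads of ATP8 may thus have been left out or counted elsewhere in PA_1 and IVF_1, which was not tested. A difference in the mitochondrial sequence between the lines may also play a part and was not tested.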

How the results depend on the processing

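Scaling with RLE size factors, no filter on low counts, DESeq2, limma-voom, the replicate number as a block, the libraries of the compared lines only, and mitochondrial genes left out (added after seeing the data) each kept the counts of called genes within 1.5 times. Replicate differences correlated across genes at -0.344 for PA_1 and PA_3, 0.191 for PA_1 and IVF_1 and -0.265 for PA_3 and IVF_1. The replicate numbers thus did not pair the libraries in 1 direction. With the numbers of PA_3 exchanged, each of these correlations would be positive, which a factor shared by the libraries could give. Such a factor under another numbering is not excluded, and the block, run with the given numbers only, could not remove it. The libraries of PA_1 departed more from counting error (chi-square per degree of freedom 11.5, against 4.27 in PA_3 and 2.78 in IVF_1), while the lines share 1 estimate of the spread. With the replicate block 4677, 7798, 5461 and 6673 genes were called in PA_1 against IVF_1, PA_3 against IVF_1, PA_1 against PA_3 and the mean of the PA lines against IVF_1. DESeq2 called fewer, with 3386, 6323, 4109 and 5320 genes in the same order, and gave overlaps of 1087 higher and 1232 lower. A 2-fold minimum, which by construction lowers counts, left 1006, 1991, 1264 and 1293 genes in the same order, and overlaps of 316 higher and 268 lower. Splitting the IVF_1 libraries between the PA lines (added after seeing the data) gave overlaps of 748 higher and 905 lower with library 1 for PA_1 and library 2 for PA_3, and 690 and 799 with the libraries exchanged. Leaving out 1 library, with the lone library of a line assumed to vary like the others, gave 2307 to 5812 genes in PA_1 against IVF_1, 3406 to 6496 in PA_1 against PA_3 and 3907 to 8105 for the mean of the PA lines. It gave overlaps of 761 to 2017 higher and 833 to 2148 lower genes. The X median minus the autosomal median ranged from 0.053 to 0.097 in PA_1 against IVF_1, 0.099 to 0.121 in PA_3 against IVF_1 and -0.060 to -0.032 in PA_1 against PA_3. With an estimated correlation camera called 0 lists in each of the 4 comparisons, with 5, 3, 1 and 5 lists at an unadjusted p under 0.05, in place of 11, 8, 5 and 9 lists. A higher correlation cannot account for each lost call. With the estimate, camera also takes its p from the 3 residual degrees of freedom, which it does not with the preset. For genes expressed from the paternal allele in PA_1 against IVF_1, the unadjusted camera p was 9e-14 with the preset and 0.004 with the estimate. These p-values therefore do not measure the correlation alone. In PA_1 against IVF_1 the estimate was -0.023 for genes expressed from the paternal allele and -0.021 for heat shock and unfolded protein genes. It was -0.015 for FGF and ERK targets, and all of these lie below the preset of 0.01. For the neuroectoderm and respiratory chain lists it was higher, at 0.259 and 0.292. Fry called 14 lists in PA_1 against IVF_1, 16 in PA_3 against IVF_1, 6 in PA_1 against PA_3 and 14 for the mean of the PA lines. It turned the DNA methylation list in PA_1 against IVF_1 downward (adjusted p = 0.016). The lowest correlation within a line was 0.991 and the highest between lines 0.969 with log2(CPM + 0.1), and these were 0.985 and 0.784 over the 1000 most variable genes, in place of 0.995 and 0.982. Except for the 2-fold minimum, the cause was not tested. Of 9992 values of single named genes under the alternatives, 9572 stayed on the same side of the threshold, and 302 lost and 118 gained a call. The sign differed in 121 values, all of genes not called in either fit, and 110 of these came from leaving out 1 library. Settings for tables without counts were not run, since counts were present, and the mean of the PA lines uses all libraries, so it has no value for the compared lines only.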

Other observations

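The list of silent genes below and the chromosome test were chosen after the results were seen, as were the genes named in this part.

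A long noncoding RNA gene without a symbol (ENSSSCG00000051274, chromosome 7, 121656237 to 121691190), near DLK1, stood at 808 ± 23.9 CPM in PA_1, 496 ± 28.0 in PA_3 and 270.3 ± 21.4 in IVF_1 (n = 2 libraries per line). It was called higher in PA_1 (log2 fold change 1.58, SE 0.072, adjusted p = 5.8e-11) and in PA_3 (0.87, SE 0.071, adjusted p = 3.7e-08) than in IVF_1, where DLK1 was higher. In mammals this region holds RNA genes expressed from the maternal allele, opposite to DLK1.

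Genes under 0.2 CPM in both PA lines and at 5 CPM or more in IVF_1 numbered 9, while 0 genes were silent in PA_3 and IVF_1 and expressed in PA_1, and 2 were silent in PA_1 and IVF_1 and expressed in PA_3. Genes silent in a single line and expressed in the other lines numbered 6 for PA_3, 2 for PA_1 and 1 for IVF_1. The gene silent in IVF_1 alone had counts in replicate 1 of each PA line only. Of the 9 genes, 4 were on the list of genes expressed from the paternal allele (SNRPN, PEG10, SGCE and DIRAS3). SGCE lies beside PEG10, and the unnamed genes ENSSSCG00000042919 (21.7 ± 1.09 CPM in IVF_1) and ENSSSCG00000048420 (491 ± 28.6 CPM in IVF_1) lie on the scaffold of SNRPN. KBTBD6 on chromosome 11 (25.1 ± 1.30 CPM in IVF_1), ENSSSCG00000029347 on chromosome 2 (18.1 ± 1.68 CPM) and ENSSSCG00000037347 on an unplaced scaffold (6.87 ± 1.85 CPM) had at most 2 counts in a PA line. The allele that these 3 genes are expressed from was not tested.

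Gain or loss of a whole autosome as a source of the differences between lines is argued against, since the autosomal median log2 fold change farthest from 0 in the 3 comparisons of lines was 0.066 (chromosome 11, PA_3 against IVF_1, 241 genes), where 1 extra copy in all cells would give 0.58. The X chromosome was not part of this test. Copy changes of parts of chromosomes, or in a share of the cells, were not tested.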
